A study of Capra hircus with 25 samples.

How the data were processed

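Liver of goat kids (Capra hircus, the Laiwu black breed) was profiled for microRNAs (miRNAs, short RNAs that repress messenger RNAs) at 1 day and at 2, 4, 8 and 12 weeks of age, with 5 libraries per age and 25 in all. Per the labels' protocols, frozen liver was extracted with Trizol and 5 ug of total RNA went into each library, with a kit made for stranded total RNA. A step that selects small RNAs is not given in the sources used here. Bowtie 1.1.1 is named in the submitters' processing notes. The genome build, the miRNA annotation, adapter trimming and the rule for reads that match several miRNAs are not given in the sources used here.

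The deposited values are in RPM, the reads of each miRNA scaled to 1 shared library total, 1 column per library and 463 entries, of which 434 carry goat names (prefix chi-) and 29 sheep names (prefix oar-). The unit was read from the values, since no header or label names it. Each column summed to between 1010981 and 1018216. Within each library all non-zero values were whole multiples of 1 step, the value of 1 read, to within 0.1 read in 100% of values in every library. The reads recovered in this way numbered 7169464 to 12096213 per library, with a median of 9526470, and 422 to 442 miRNAs had at least 1 read. A single read was worth 0.0838 to 0.142 RPM. A miRNA with no read in a library is limited by a count of 0 to below 3 reads, or 0.251 to 0.425 RPM, which covers counting error only. Column sums above that shared total leave open that some reads were counted for several miRNAs. Near-identical entries (miR-199a-3p with miR-199b-3p, miR-92a-3p with miR-92b, and sheep-named entries beside goat entries of the same miRNA) can share or divide reads, and their values are uncertain for that reason. The 5p arms of miR-376b, miR-376e and miR-376c also had nearly the same values (43.8, 43.8 and 44.0 RPM at 1 day). Near-identical entries were counted separately. miR-199b and miR-199c had identical values in every library for both arms. With only such exact copies counted once, 405 tested miRNAs hold 403 distinct ones, and 268 of the 269 calls at 12 weeks against 1 day are distinct.

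Before the data were examined, the groups, the tests, the rule for named miRNAs, 15 miRNA lists and the alternatives were fixed. The plan assumed raw counts and named a second test for normalized values, which is the one used. Values were taken as log2(RPM + 1), miRNAs at 1 RPM or more in at least 5 libraries were kept (405 miRNAs, 58 left out), and limma 3.58.1 with a mean-dependent variance trend was fitted to all 25 libraries with 1 mean per age. An F test compared the 5 ages, and 7 contrasts compared pairs of ages. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are on the log2(RPM + 1) scale, which understates the change of low miRNAs. The deposited scaling to a library total was kept for the main values. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 13 lists and 7 comparisons (91 tests). The share of reads in the 10 most abundant miRNAs was compared by an exact two-sided permutation test.

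The named miRNAs are, for 12 weeks against 1 day, the 10 largest increases and 10 largest decreases that were called, had a mean of at least 10 RPM in the higher group and no overlap between the libraries of both ages. For each other pair the same rule takes 5 and 5. It further takes the 10 most abundant miRNAs, up to 4 of the most abundant members of each list, and the 5 smallest p of the F test. Other miRNAs named here were chosen after their values were seen, among them oar-miR-194, miR-29b-5p, miR-133b, miR-206, miR-146b-3p, miR-199b-5p and miR-143-5p. The lists were the let-7, miR-29 and miR-30 families, the miR-17-92 group with its paralogs, the imprinted DLK1-DIO3 cluster, an imprinted growth list, lipid metabolism miRNAs, and markers of hepatocytes, erythroid cells, leukocytes, mesenchymal cells, endothelium, biliary epithelium, striated muscle, and pancreas and endocrine cells.

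Alternatives were scaling by the median ratio over miRNAs (RLE), no filter, a mean of at least 10 RPM, pseudocounts of 0.1 and 10, only the 2 ages compared, a log2 change of at least 1, the replicate number as a block, leaving out each library, and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were TMM scaling, edgeR 4.0.16's quasi-likelihood test on the recovered reads, setting aside the 10 most abundant miRNAs, leaving out 4-week replicates 1 and 2 together, and counting identical arm ratios once. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and figures from matplotlib 3.10.9.

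The tests were tested on simulated data made for 12 weeks against 1 day from the means, depths and dispersions of the 405 miRNAs, with 200 of them changed. When simulated reads were scaled by the depth they were drawn at, limma recovered 58.2% of the 1.5-fold, 82.1% of the 2-fold and 98.5% of the 4-fold changes, with 3 false calls among 162. Scaled by their own total, as the deposited values are, the same reads gave 46 false calls among 199, since changed abundant miRNAs shift all others. RLE scaling of those values left 4 false calls among 160. Simulated increases and decreases were equal in number and all other miRNAs were left unchanged. The middle change was thus 0, which median-ratio scaling presupposes. Its low number of false calls was therefore built in and does not show which scaling is right for the real data. With no simulated change limma, edgeR and DESeq2 made 0 calls in the comparison, and in the test among the 5 ages limma and edgeR made 0 and DESeq2 3. With 2 lists raised 2-fold, camera called both and no other list. Correlation between miRNAs was not among the quantities from which the simulated data were made. In the real data the estimated correlation within lists ran from 0.063 (hepatocyte) to 0.762 (biliary epithelial), with 0.574 for the DLK1-DIO3 list. The simulated list test therefore cannot show how camera at its preset correlation behaves for members that vary together.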

Results

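Liver miRNAs were measured at 5 ages from birth to 12 weeks in Laiwu black goat kids, a breed of domestic goat, to follow the liver miRNA profile over early life. The values are normalised read counts (RPM) of 463 miRNAs in 25 libraries, 5 per age. Between 7169464 and 12096213 miRNA reads lay behind each library. No label says that the 5 libraries of an age came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. No pair of libraries within an age was close enough to be the same library read again, which leaves open repeat preparations of 1 liver. Names without a prefix are the goat (chi-) entries of the table. Named values are means ± SD over 5 libraries, and ± after a log2 change is the standard error of the fit.

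The liver profile was dominated by a few miRNAs. miR-122, the main miRNA of hepatocytes, had 158010 ± 15470 RPM at 1 day and 168620 ± 23250 RPM at 12 weeks (n = 5 each), and did not pass the test (log2 change 0.09 ± 0.12, adjusted p = 0.512, limma). miR-143-3p, a miRNA of smooth muscle and other mesenchymal cells, came next with a mean of 118260 RPM over all libraries, followed by miR-21-5p with 83846 RPM and miR-30a-5p with 81458 RPM. Neither miR-143-3p, miR-21-5p nor miR-30a-5p passed the test at 12 weeks against 1 day (log2 changes −0.15 ± 0.19, −0.26 ± 0.16 and 0.26 ± 0.14), and neither did miR-148a-3p, miR-194 or let-7f-5p. This holds for the deposited scaling: median-ratio scaling called miR-122 (log2 change 0.68), miR-30a-5p (0.84), miR-148a-3p (0.69), miR-194 (0.58) and let-7f-5p (0.73) higher, and neither miR-143-3p (0.44) nor miR-21-5p (0.32). miR-26a-5p rose from 43302 ± 2602 to 71017 ± 7861 RPM (1.63-fold, adjusted p = 4.47e-08) and miR-101-3p from 25365 ± 4340 to 35013 ± 3758 RPM (1.39-fold, adjusted p = 0.00125). miR-30e-5p was lower at 12 weeks, 26527 ± 2291 against 34706 ± 7970 RPM (adjusted p = 0.019), a call lost in 2 of 10 fits that left out 1 library (adjusted p = 0.0786 without 1-day replicate 5) and turned in sign by median-ratio scaling (log2 change 0.23). Together the 10 most abundant miRNAs took 64.6% ± 0.93 of reads at 1 day and 67.9% ± 0.75 at 12 weeks, a difference of 3.32 percentage points (exact two-sided permutation test, p = 0.00794, the smallest that 252 arrangements can give).

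Of 405 miRNAs tested, 262 differed among the 5 ages (F test, limma, adjusted p under 0.05). The 5 smallest p belonged to miR-542-3p (adjusted p = 4.27e-13), miR-29a-3p (1.02e-10), miR-532-5p (1.31e-09), miR-335-5p (1.42e-08) and the sheep-named oar-miR-26a (1.98e-08). miR-542-3p had 7039 ± 665 RPM at 1 day and 1425 ± 262 RPM at 12 weeks, and miR-29a-3p had 3461 ± 471 and 9271 ± 770 RPM. Among the 262, the mean was highest at 1 day for 182 and at 12 weeks for 32. The means of 106 fell at every step of age, those of 23 rose at every step, and 133 did neither. These directions rest on the deposited scaling: after median-ratio scaling 247 were called, 191 of them shared, with the highest mean at 1 day for 95 and at 12 weeks for 91, and 54 fell and 57 rose at every step. In a principal component analysis of the deposited scaling the first component held 50.8% of the variance and ordered the libraries by age, except that 4-week replicates 1 and 2 (3.04 and 5.12) lay near the 8-week libraries and 4-week replicates 3, 4 and 5 (−4.88, −3.85 and −2.39) beside the 2-week libraries. Median-ratio scaling divides libraries by 1.13 to 1.34 at 1 day and by 0.74 to 0.88 at 12 weeks. For 4-week replicates 1 and 2 it divides by 0.91 and 0.82, and for replicates 3, 4 and 5 by 1.15, 1.18 and 1.11. How far the first component follows the scaling was not tested.

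**Figure D1:**
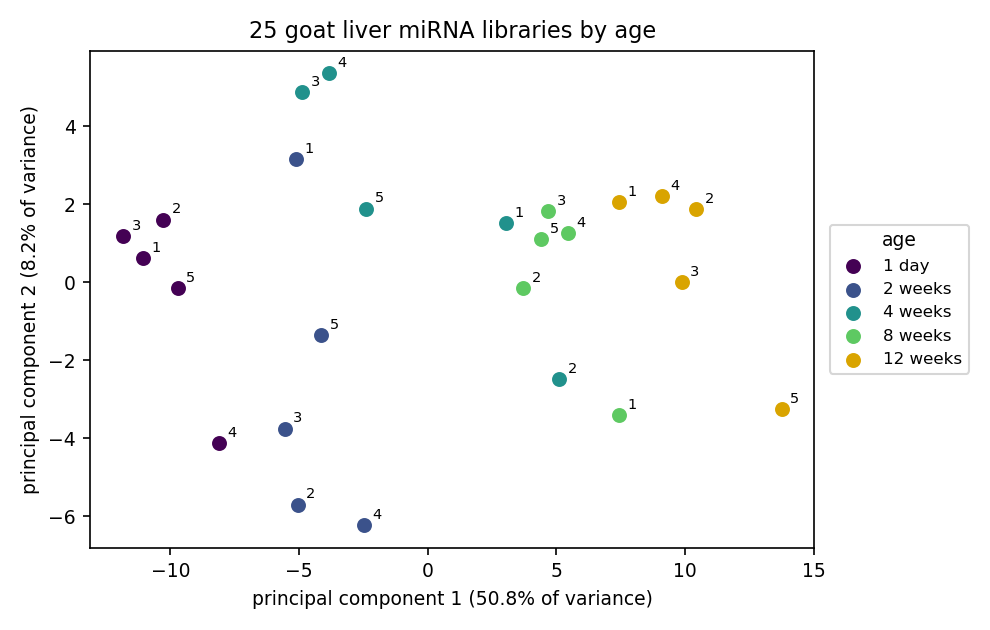
Scores of the 25 libraries on the first (x axis, 50.8% of variance) and second (y axis, 8.2% of variance) principal components of log2(RPM + 1) over 405 miRNAs; each point is a library, coloured by age and marked with its replicate number. The 1-day libraries lie at the left and the 12-week libraries at the right, and 4-week replicates 1 and 2 lie at 3.04 and 5.12 on the x axis.

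At 12 weeks against 1 day, the widest span, the muscle-associated miR-133a-3p and miR-1 rose most. miR-133a-3p went from 49.6 ± 26.8 to 395 ± 71.9 RPM (8.65-fold, log2 change 3.11 ± 0.31, n = 5 each, adjusted p = 1.29e-08) and miR-1 from 1144 ± 591 to 9221 ± 3086 RPM (8.57-fold, adjusted p = 3.81e-08). miR-150, a lymphocyte miRNA, rose 4.95-fold to 236 ± 85.5 RPM, and miR-29a-3p, of a family that represses collagen messenger RNAs, rose 2.69-fold. miR-335-5p, which lies within the imprinted gene MEST, fell from 13876 ± 2210 to 2996 ± 674 RPM (log2 change −2.23 ± 0.20, adjusted p = 1.37e-09). miR-483, which lies within the gene of the fetal growth factor IGF2, fell from 69.4 ± 33.0 to 10.8 ± 5.08 RPM (log2 change −2.56 ± 0.33, adjusted p = 2.91e-07).

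The other large increases were in oar-miR-26a (2.93-fold), miR-708-5p (2.78-fold), miR-365-3p (2.69-fold), oar-let-7f (2.61-fold), the immune-associated miR-146b-5p (2.59-fold) and oar-let-7a (2.48-fold). The 3 sheep-named entries stand beside more abundant goat entries of the same miRNAs and may divide reads with them, so their levels are uncertain. The largest decrease was in miR-34c-5p, from 78.7 ± 17.2 to 11.1 ± 4.93 RPM (log2 change −2.80 ± 0.40), and its neighbour miR-34b-3p fell by 2.31 on the log2 scale; both belong to a family induced by p53. miR-542-3p fell by 2.32 on the log2 scale. These rankings hold among called miRNAs with at least 10 RPM in the higher group and no overlap between libraries, and a DLK1-DIO3 member outside these limits had −2.40. The remaining 5 of the 10 largest decreases within them, miR-496-3p, miR-410-3p, miR-493-5p, miR-493-3p and miR-433, belong to the DLK1-DIO3 cluster and had log2 changes from −2.32 to −2.16. Every one of the 20 named increases and decreases was called with the same sign in each of the 10 fits that left out 1 library.

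In total 269 of 405 miRNAs were called at 12 weeks against 1 day, 47 higher and 222 lower; 139 of them changed at least 2-fold. The libraries of both ages did not overlap for 215 miRNAs, against 0.79% of miRNAs by chance. This split rests on the scaling. The median log2 change over the 405 miRNAs was −0.54 in the deposited values and −0.01 after median-ratio scaling, which gave 118 higher and 132 lower of 250 called. After that scaling the 10 named increases had log2 changes of 1.88 to 3.69 and the 10 named decreases −2.24 to −1.59, and all 20 were called.

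**Figure D2:**
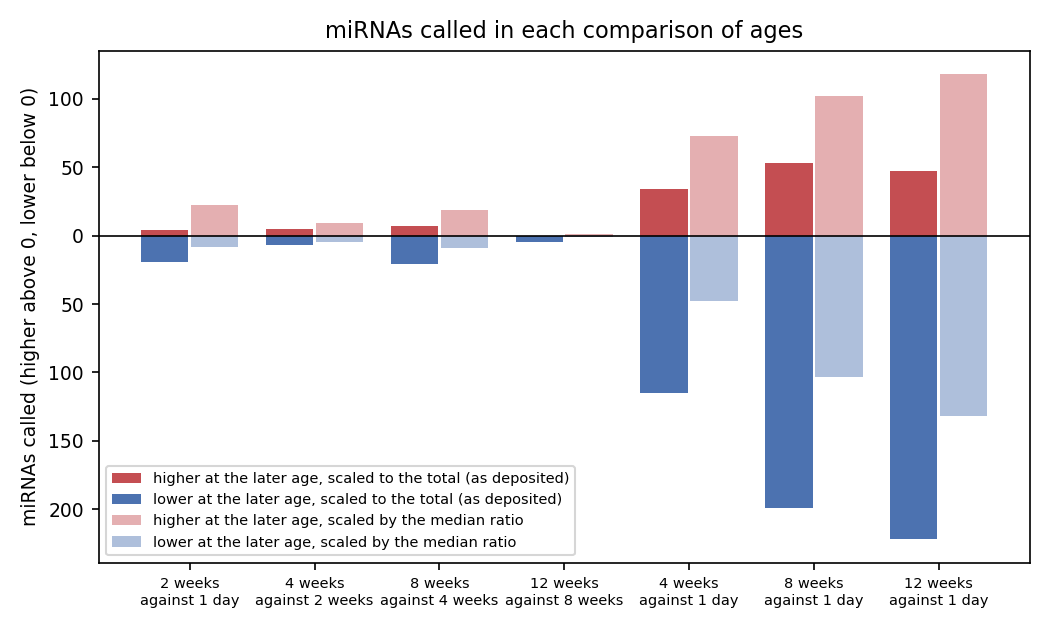
Number of miRNAs called (y axis, counts, higher at the later age above 0 and lower below 0) in each of the 7 comparisons of ages (x axis), with the values scaled to the library total as deposited (dark bars) and by the median ratio over miRNAs (pale bars). For 12 weeks against 1 day the split was 47 higher and 222 lower as deposited, and 118 higher and 132 lower by the median ratio.

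The DLK1-DIO3 cluster, an imprinted group of miRNAs expressed from the maternal copy, was lower at 12 weeks: 74 of 76 tested members fell and none rose (75 lower when adjusted over the list alone). Its most abundant members, miR-379-5p (4143 ± 196 to 1934 ± 239 RPM), miR-411a-5p (3703 ± 236 to 1678 ± 202 RPM), miR-369-3p (2836 ± 291 to 1087 ± 179 RPM) and miR-127-3p (1829 ± 230 to 812 ± 167 RPM), had log2 changes of −1.39 to −1.11. The median of the list was −1.38, and −0.84 after median-ratio scaling, where 63 members were still called lower. Set against other miRNAs the list was lower by camera (adjusted p = 5.04e-11), with adjusted p = 0.494 with an estimated correlation.

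The miR-29 family was higher: 5 of 6 members rose, also when adjusted over the list alone. miR-29b-3p rose 2.42-fold to 217 ± 48.5 RPM, miR-29c-3p 1.61-fold and miR-29a-5p 1.63-fold, while miR-29b-5p, near 1.8 RPM at both ages, did not pass. The list was called by camera (adjusted p = 5.45e-05; adjusted p = 0.196 with an estimated correlation). Of 6 striated muscle miRNAs 4 rose (miR-1, miR-133a-3p, miR-133a-5p and miR-133b). miR-499-5p, which heart and slow-twitch muscle carry, fell from 48.9 ± 4.92 to 18.9 ± 1.29 RPM, and miR-206 of skeletal muscle stood at 0.392 ± 0.266 and 2.49 ± 2.64 RPM without passing the test, but was called higher after median-ratio scaling (adjusted p = 0.0387), which gave 5 higher and 1 lower. The muscle list had adjusted p = 0.000883 by camera and adjusted p = 0.271 with an estimated correlation.

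Of 9 leukocyte miRNAs 4 rose: miR-150, miR-146b-5p, miR-146b-3p and the abundant miR-146a (1203 ± 328 to 2026 ± 702 RPM, adjusted p = 0.0246, lost in 2 of 10 fits, adjusted p = 0.0923 without 12-week replicate 5). The abundant miR-342-3p (log2 change 0.00 ± 0.13), miR-223-3p (0.52 ± 0.30) and miR-155-5p (−0.14 ± 0.19) did not pass; after median-ratio scaling all 3 were higher, and 8 of the 9. The leukocyte list had adjusted p = 0.000975 by camera and adjusted p = 0.271 with an estimated correlation. Among 8 hepatocyte miRNAs only oar-miR-194 was called higher (1.72-fold), while miR-122, miR-148a-3p, miR-194 and miR-192-5p lay within 0.10 of 0 on the log2 scale; median-ratio scaling called 7 of 8 higher. The hepatocyte list had adjusted p = 0.0438 by camera and adjusted p = 0.283 with an estimated correlation, and 2 of 10 fits that left out 1 library lost it (adjusted p = 0.0645 without 1-day replicate 3).

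Erythroid miRNAs moved apart. miR-451-5p rose from 1486 ± 290 to 3258 ± 613 RPM (adjusted p = 0.00045), miR-144-5p and miR-363-3p fell (log2 changes −0.50 ± 0.21 and −0.56 ± 0.20), and miR-144-3p had −0.57 ± 0.33 without passing. Both decreases were lost after median-ratio scaling, and leaving out 1 library ended that of miR-144-5p in 6 of 10 fits (adjusted p = 0.168 without 12-week replicate 2) and that of miR-363-3p without 1-day replicate 2 (0.0514). The endothelial miR-126-3p and miR-126-5p were both lower (log2 changes −0.27 ± 0.11 and −0.64 ± 0.13). After median-ratio scaling miR-126-3p was called higher (0.31) and miR-126-5p was not called, and 5 of 10 fits that left out 1 library lost miR-126-3p (adjusted p = 0.0684 without 12-week replicate 1). In the biliary epithelial list miR-200a (−0.77 ± 0.20) and miR-429 (−1.05 ± 0.28) fell, while miR-200b (−0.51 ± 0.24) and miR-200c (0.21 ± 0.36) did not pass; none was called after median-ratio scaling. Of 10 mesenchymal miRNAs, 2 were lower (miR-199b-5p and miR-143-5p, named after their values were seen; 0 when adjusted over the list alone; neither called after median-ratio scaling, where miR-143-5p turned to 0.14), with miR-143-3p, miR-199a-3p, miR-199b-3p and miR-199a-5p not called; median-ratio scaling called 2 of the 10 higher and 0 lower.

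In the let-7 family, which times development, 4 of 20 members rose and 7 fell. let-7a-5p rose from 16514 ± 1127 to 20583 ± 751 RPM and let-7i-5p fell from 9413 ± 1273 to 6695 ± 430 RPM, while let-7f-5p and let-7g-5p did not pass (log2 changes 0.14 ± 0.08 and 0.05 ± 0.07). Median-ratio scaling gave 10 higher and 2 lower, and let-7i-5p was then not called. Of 11 miR-30 members 2 rose and 6 fell, among them miR-30b-5p (1.34-fold higher) and miR-30c-5p (log2 change −0.70 ± 0.14), against 4 and 0 after median-ratio scaling, where miR-30c-5p was not called. Of 21 members of the miR-17-92 group and its paralogs 11 fell and none rose, with miR-25-3p (−0.24 ± 0.10) and miR-93-5p (−0.37 ± 0.13) called and miR-92a-3p and miR-92b not; median-ratio scaling gave 8 higher and 3 lower, with miR-25-3p called higher and miR-93-5p not called. Leaving out 1 library ended the call of miR-25-3p in 6 of 10 fits (adjusted p = 0.102 without 1-day replicate 3) and that of miR-93-5p without 12-week replicate 2 (0.0517). Of 14 lipid metabolism miRNAs 2 rose and 6 fell. miR-103-3p rose 1.89-fold, miR-378-3p fell by 0.93 and miR-27b-3p by 0.36 on the log2 scale, and miR-27a-3p did not pass; the split was 4 higher and 3 lower after median-ratio scaling, where miR-378-3p and miR-27b-3p were not called. The 4 pancreas and endocrine miRNAs, miR-7-5p, miR-7-3p, miR-217-5p and miR-216b, were not called, though 2 were higher after median-ratio scaling. The imprinted growth list held miR-483 alone. Except where given, counts adjusted over the list alone were the same. Of these last 10 lists camera called none of the 8 it tested, and the endothelial and imprinted growth lists were too short to test; for the let-7, erythroid, mesenchymal, biliary, pancreas, lipid and miR-30 lists camera's direction was up, since it compares with other miRNAs, while the median was below 0.

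**Figure D3:**
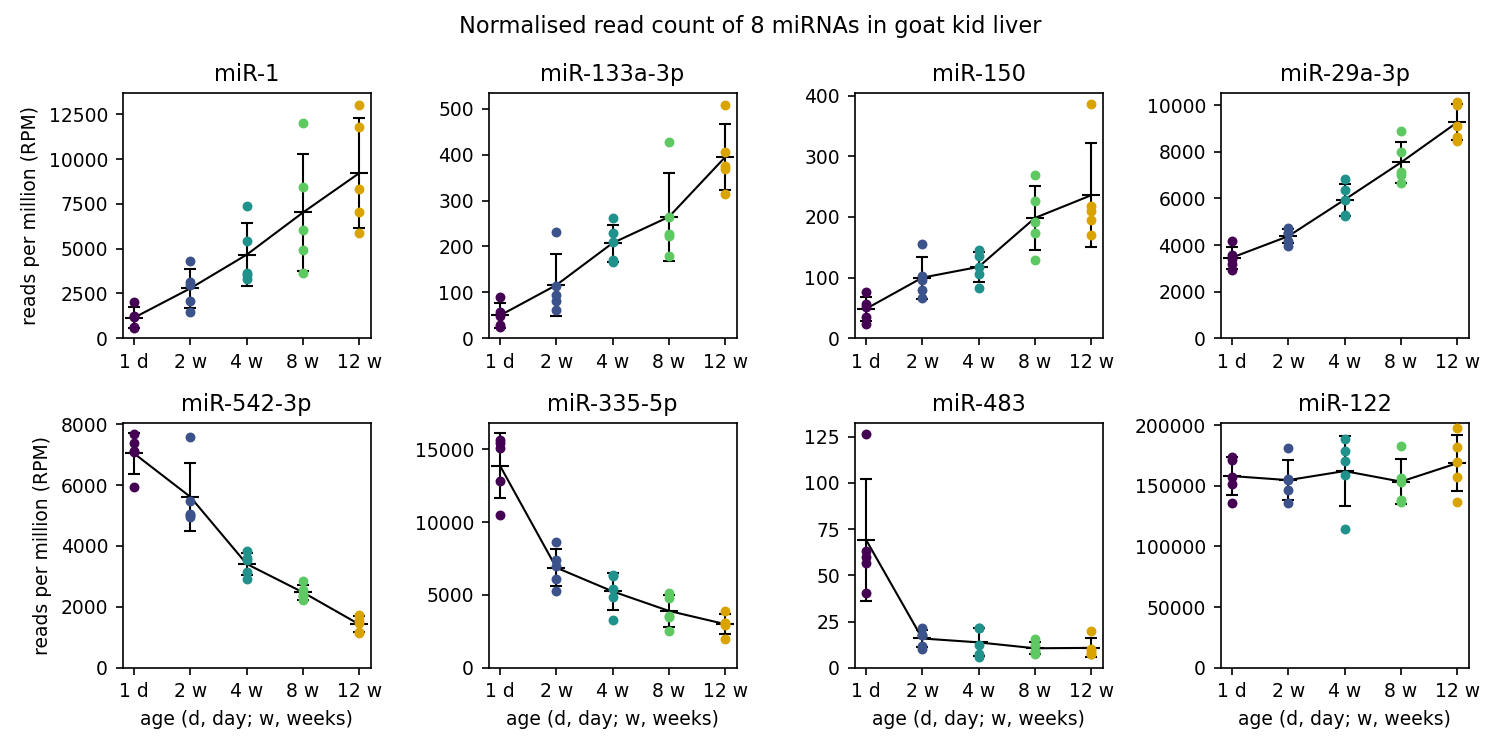
Normalised read count (y axes, RPM, from 0) of 8 miRNAs at the 5 ages (x axes, evenly spaced and not to scale in time); points are libraries, and the black line and bars give the mean and SD of 5 libraries. miR-1, miR-133a-3p, miR-150 and miR-29a-3p were higher at 12 weeks than at 1 day, miR-542-3p, miR-335-5p and miR-483 were lower, and miR-122 did not pass the test.

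At 8 weeks against 1 day, the rankings hold among called miRNAs with at least 10 RPM in the higher group and no overlap between libraries. There miR-1 (6.27-fold, to 7020 ± 3290 RPM), miR-133a-3p (5.62-fold) and miR-150 (4.22-fold) rose most, followed by miR-146b-5p (2.51-fold) and the erythroid miR-451-5p (2.46-fold, to 3654 ± 616 RPM). Within these limits miR-483 (log2 change −2.54 ± 0.33), miR-34c-5p (−2.16 ± 0.40), miR-1185-3p (−1.92 ± 0.32), miR-335-5p (−1.86 ± 0.20) and miR-34b-3p (−1.84 ± 0.37) fell most. A DLK1-DIO3 member outside them had a log2 change of −2.345. In the DLK1-DIO3 cluster 68 of 76 members fell and 71 when adjusted over the list alone (camera adjusted p = 1.96e-07; adjusted p = 0.64 with an estimated correlation), and 5 of 6 miR-29 members rose (7.71e-05 by camera; adjusted p = 0.196 with an estimated correlation). In all 252 miRNAs were called, 53 higher and 199 lower, or 102 higher and 103 lower after median-ratio scaling.

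At 4 weeks against 1 day, the rankings again hold among called miRNAs with at least 10 RPM in the higher group and no overlap between libraries. There miR-133a-3p (4.54-fold, to 207 ± 40.3 RPM), miR-1 (4.31-fold), miR-150 (2.54-fold), oar-let-7f (2.21-fold) and miR-490 (2.06-fold, to 16.7 ± 2.06 RPM) rose most. miR-135b-5p fell most, from 497 ± 91.3 to 89.3 ± 39.5 RPM (log2 change −2.53 ± 0.46, adjusted p = 0.000216), with miR-483 (−2.31 ± 0.33), miR-335-5p (−1.43 ± 0.20), miR-34b-3p (−1.39 ± 0.37) and miR-410-3p (−1.07 ± 0.23). In the DLK1-DIO3 cluster 31 of 76 members fell and 35 when adjusted over the list alone (camera adjusted p = 0.000216; adjusted p = 0.849 with an estimated correlation). In all 149 miRNAs were called, 34 higher and 115 lower, or 73 higher and 48 lower after median-ratio scaling. Without 4-week replicates 1 and 2, which lay apart from the other 4-week libraries, 87 were called, 37 higher and 50 lower, and in the DLK1-DIO3 cluster 5 members were lower, the median went from −0.49 to −0.20 and the list was not called (camera adjusted p = 0.0565).

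At 2 weeks against 1 day, miR-483 fell from 69.4 ± 33.0 to 15.9 ± 4.58 RPM (adjusted p = 0.000719), miR-135b-5p from 497 ± 91.3 to 151 ± 51.1 RPM (log2 change −1.77 ± 0.46), and miR-335-5p from 13876 ± 2210 to 6875 ± 1267 RPM (−1.02 ± 0.20). miR-197-3p (−0.91 ± 0.17) and miR-500-5p (−0.65 ± 0.15) completed the 5 largest separated decreases among miRNAs with at least 10 RPM in the higher group. Below that level miR-129-5p, named after its values were seen, was also called and separated (−1.10 ± 0.26, from 4.46 to 1.48 RPM). The 4 increases, named after their values were seen, were miR-1 (2.54-fold), miR-133a-3p (2.32-fold), miR-150 (2.11-fold) and miR-29a-3p (1.27-fold), each with overlapping libraries. In all 23 miRNAs were called, 4 higher and 19 lower, or 22 higher and 8 lower after median-ratio scaling. The call of miR-135b-5p was lost without 1-day replicate 1 (adjusted p = 0.0572) and with TMM scaling (log2 change −1.58, adjusted p = 0.0529), and 15 miRNAs were called in all without 1-day replicate 1 or without 2-week replicate 4.

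At 4 weeks against 2 weeks, oar-miR-26a rose 1.79-fold to 365 ± 86.8 RPM, miR-204-3p 1.53-fold to 11.4 ± 2.08 RPM and miR-29a-3p 1.35-fold to 5947 ± 681 RPM. miR-542-3p fell from 5612 ± 1109 to 3411 ± 371 RPM (log2 change −0.71 ± 0.13, adjusted p = 0.00333) and miR-30e-3p from 392 ± 56.9 to 268 ± 22.6 RPM (−0.54 ± 0.14, not called after median-ratio scaling, adjusted p = 0.13). These are the called miRNAs with at least 10 RPM in the higher group and no overlap between libraries. Outside these limits, larger falls were called for miR-34c-3p (−1.53 ± 0.35), miR-34b-3p (−1.49 ± 0.37), miR-34c-5p (−1.42 ± 0.40) and miR-502b-5p (−0.83 ± 0.18), named after their values were seen. Libraries overlapped for miR-34b-3p and miR-34c-5p, and the others lay below 10 RPM. In all 12 miRNAs were called, 5 higher and 7 lower, or 9 higher and 5 lower after median-ratio scaling. With only the 2 ages in the limma fit 0 were called (55 at an unadjusted p under 0.05; DESeq2 called 18 and edgeR 17 with all ages), and without 4-week replicates 1 and 2 the count was 22. Leaving out 1 library ended the calls of miR-204-3p and miR-30e-3p in 7 of 10 fits each, up to adjusted p = 0.117 without 2-week replicate 3, and that of miR-29a-3p without 4-week replicate 4 (adjusted p = 0.0508).

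At 8 weeks against 4 weeks, miR-29b-3p rose 1.99-fold from 107 ± 30.1 to 211 ± 32.8 RPM (adjusted p = 0.00105), miR-148a-5p 1.40-fold, miR-140-5p 1.39-fold and miR-22-3p 1.37-fold to 15290 ± 1726 RPM. miR-411b-5p of the DLK1-DIO3 cluster fell from 63.7 ± 15.7 to 30.9 ± 7.53 RPM (log2 change −1.01 ± 0.22), and miR-450-3p (−0.73 ± 0.18), miR-340-5p (−0.62 ± 0.15), miR-100-5p (−0.58 ± 0.14) and miR-660 (−0.55 ± 0.12) fell. They were the largest changes among called miRNAs with at least 10 RPM in the higher group and no overlap between libraries. Of the calls outside these limits, oar-miR-431 fell most (−1.49 ± 0.25, from 4.8 to 1.06 RPM) and miR-146a rose most (2.01-fold, overlapping libraries). Both were named here after their values were seen. After median-ratio scaling miR-100-5p (adjusted p = 0.0938) and miR-340-5p (adjusted p = 0.0651) were no longer called. In all 28 miRNAs were called, 7 higher and 21 lower, or 19 higher and 9 lower after median-ratio scaling, and 3 with only the 2 ages in the fit. The count depended on single 4-week libraries: it was 86 without 4-week replicate 2, 7 without 4-week replicate 3, and 114 without 4-week replicates 1 and 2. Leaving out 1 library ended the call of miR-148a-5p in 8 of 10 fits (adjusted p = 0.151 without 4-week replicate 4; edgeR 0.0568), that of miR-450-3p in 3 (0.0828 without 4-week replicate 3) and that of miR-340-5p in 1 (0.0619 without 4-week replicate 3).

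At 12 weeks against 8 weeks, miR-542-3p fell from 2477 ± 240 to 1425 ± 262 RPM (log2 change −0.81 ± 0.13, adjusted p = 0.000387) and the erythroid miR-144-5p from 126 ± 13.8 to 66.0 ± 17.0 RPM (−0.96 ± 0.21, adjusted p = 0.0175). The other 3 of the 5 miRNAs called, named after their values were seen, also fell: miR-424-5p (−0.87 ± 0.17), miR-125a-3p (−0.81 ± 0.19) and miR-424-3p (−0.77 ± 0.19). None rose by limma, where 77 miRNAs had an unadjusted p under 0.05; DESeq2 called 5 higher and 11 lower, and edgeR 1 lower. The DLK1-DIO3 list was lower by camera (adjusted p = 3.27e-11; adjusted p = 0.494 with an estimated correlation), though 0 members were called over all miRNAs and 16 when adjusted over the list alone. After median-ratio scaling 2 miRNAs were called, 1 in each direction, miR-542-3p (−0.65, adjusted p = 0.0686) and miR-144-5p (−0.80, adjusted p = 0.0686) no longer among them. Without 8-week replicate 1 the count was 15 and without 12-week replicate 2 it was 2, where miR-144-5p was lost (adjusted p = 0.0761).

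Over the 7 comparisons camera called 32 of 91 list tests, 24 up and 8 down relative to other miRNAs. The DLK1-DIO3 list made up 7 of these 8, but at 2 weeks against 1 day (adjusted p = 0.0118; adjusted p = 0.849 with an estimated correlation) no member was called, and 2 of 10 fits that left out 1 library lost the list (adjusted p = 0.266 without 2-week replicate 5). At 4 against 2 weeks (adjusted p = 0.00159; adjusted p = 0.849 with an estimated correlation) 0 of its 76 members were called, and its fall came from 4-week replicates 1 and 2: without both the median turned from −0.19 to 0.10 and the list was not called (adjusted p = 0.967). At 8 against 4 weeks 7 members were lower (13 adjusted over the list alone; adjusted p = 1.83e-05; adjusted p = 0.785 with an estimated correlation), and 47 without those replicates. With an estimated correlation 0 of the 91 were called (15 at an unadjusted p under 0.05). The test fry, which asks whether a list's members move one way on balance without setting them against other miRNAs, called 20. Of these, 13 were among camera's 32. By fry the DLK1-DIO3 list was lower at 4, 8 and 12 weeks against 1 day, and was not called between successive ages (adjusted p of 0.0802 to 0.433).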

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

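Tests of depth, of heart and slow-twitch muscle, of mesenchymal cells for the DLK1-DIO3 cluster, of the mesenchymal list's change and of setting aside abundant miRNAs were chosen only after the results they bear on were seen, the last with its outcome not yet known. Among 175 sets of 5 libraries examined for a single library far from the others, 7 had one, where chance would give about 8.8. At 1 day, replicate 3 had 126 RPM of miR-483, with the other libraries between 40.6 and 63.2 RPM, and a mean log2 level of 7.87 for the let-7 list, with the others between 7.71 and 7.75. At 4 weeks, replicate 2 had 247300 RPM of miR-143-3p against 89360 to 103200 RPM in the others, and replicate 1 had 62350 RPM of miR-26a-5p against 50670 to 53090 RPM. At 12 weeks, replicate 2 had 386 RPM of miR-150 against 171 to 218 RPM, and replicate 1 had 19.7 RPM of miR-483 against 7.61 to 10.02 RPM. The imprinted growth list, which miR-483 makes up alone, accordingly stood at a mean log2 level of 4.37 in that 12-week library against 3.11 to 3.46.

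Most miRNAs called at 12 weeks against 1 day were lower (222 of 269), which lower depth does not account for, since mean depth at 12 weeks was 1.11 times that at 1 day. A larger share for the 10 most abundant miRNAs is not the whole cause either: with these set aside and the rest rescaled, 76.3% of calls were still lower. Scaling to a fixed total stays open and cannot be told apart from a broad fall with age. Median-ratio scaling left 52.8% of calls lower, and the mark set beforehand for scaling as the cause, 60% or less, was met. Only after that value was seen was the mark set aside, because this scaling centres changes on 0 whatever their cause; no spiked-in standard was analysed here.

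miR-1 and miR-133a-3p rose over 8-fold, and heart or slow-twitch muscle in the samples is argued against by miR-499-5p, with a log2 change of −1.32. A larger share of mesenchymal cells as a whole is argued against by a test chosen afterwards, since their list would have to rise about as far: its highest log2 change was 0.34 ± 0.16 and its median −0.27, against 3.10 ± 0.34 for miR-1. Within ages, over 25 libraries, miR-1 had Pearson's r = 0.213 with the mean of that list (permutation p = 0.342, Spearman's rho = 0.098, p = 0.662, r = 0.151 without the 2 libraries farthest from the median), between the marks set beforehand (under 0.2 against it, 0.5 or more for it) and so deciding nothing, and r = 0.453 with miR-143-3p (p = 0.00975, adjusted over 5 relations 0.0244, rho = 0.388, p = 0.0457, r = 0.483 without 2 libraries). Skeletal muscle stays open: miR-1 had r = 0.383 with miR-206 (p = 0.0608, rho = 0.285, p = 0.143, r = 0.432 without 2 libraries), which lay near the floor and was called higher after median-ratio and TMM scaling but not as deposited. In each relation the 2 libraries left out were those farthest from the median of miR-1. The relation with miR-143-3p was therefore not tested without 4-week replicate 2, which stood apart in miR-143-3p. A small smooth muscle group that the list would not show and a change with age within liver cells were not tested and stay open.

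The DLK1-DIO3 cluster fell together. Scaling alone is argued against, since 63 of 76 members were still called lower after median-ratio scaling. A smaller share of mesenchymal cells is argued against by the difference of −1.11 between the cluster's median log2 change and that of the mesenchymal list, whose lowest member (−0.69) lay above 74 of the 76 members. Loss of another cell type that expresses the cluster, and a fall with age in cells of the liver, stay open as untested explanations, and a fall with age is a hypothesis found in these same data.

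Other groupings of the libraries show how far chance can be excluded, over 100 groupings that include the real one. For the 5 ages, 1 grouping reached 262 calls, and the highest other had 96. For 12 weeks against 1 day 1 reached 269 (highest other 167), for 8 weeks against 1 day 1 reached 252 (highest other 115), for 4 weeks against 1 day 1 reached 149 (highest other 72) and for 2 weeks against 1 day 1 reached 23 (highest other 7). No other grouping reached the real count for these, the strongest result that 100 groupings can give, without adjustment over the comparisons. Regrouping libraries cannot exclude a chance difference between livers if libraries of an age are repeat preparations of 1 liver. For 12 weeks against 8 weeks 2 reached 5 calls, with 6 in the highest other. For 4 weeks against 2 weeks 4 reached 12 calls, and the highest other had 25. These 2 counts passed at the 0.05 level, without adjustment over the comparisons and with other groupings above the real one. Chance is therefore not firmly excluded for them. For 8 weeks against 4 weeks 7 groupings reached 28 calls, with up to 62, so chance is not excluded there. Whether a structure among the libraries other than age lies behind this was not tested.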

How the results depend on the processing

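TMM scaling, edgeR, setting aside abundant miRNAs and leaving out 4-week replicates 1 and 2 together were chosen after seeing the data. Scaling decided direction: for 12 weeks against 1 day, 132 of 250 calls were lower with RLE, 136 of 248 with TMM, 134 of 252 with DESeq2 and 135 of 245 with edgeR, against 222 of 269. Of the 269, 184 to 187 were called under each, counted whatever their direction. Among those named by the rule, miR-25-3p and miR-126-3p were lower as deposited and called higher under each. The splits of higher and lower calls require further calls that turned under each, which were not counted. The F test gave 200 to 285 calls under every alternative. The counts for 4, 8 and 12 weeks against 1 day stayed within 1.5 times under other scalings, filters, pseudocounts and tools. A log2 change of at least 1, a stricter demand by construction, left 139 for 12 weeks, 87 for 8 weeks and 22 for 4 weeks against 1 day, 11 for 2 weeks against 1 day, 3 for 4 against 2 weeks, 3 for 8 against 4 weeks and 0 for 12 against 8 weeks (77 at an unadjusted p by limma). For 2 weeks against 1 day a pseudocount of 10 gave 46 and DESeq2 45. With only the 2 ages in the fit, which leaves fewer libraries to estimate the spread, 4 against 2 weeks gave 0, 8 against 4 weeks 3 and 12 against 8 weeks 3. For 12 against 8 weeks RLE gave 2, TMM 1, edgeR 1 and DESeq2 16. Without 4-week replicates 1 and 2 the counts were 22 for 4 against 2 weeks, 114 for 8 against 4 weeks and 87 for 4 weeks against 1 day. Where no cause is given, the cause was not tested.

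Leaving out 1 library gave 250 to 281 for the F test, 257 to 269 for 12 weeks, 223 to 246 for 8 weeks, 109 to 163 for 4 weeks and 15 to 33 for 2 weeks against 1 day, 6 to 16 for 4 against 2 weeks, 7 to 86 for 8 against 4 weeks, and 2 to 15 for 12 against 8 weeks. Counts moved by over 1.5 times in 2 of 10 fits for 2 weeks against 1 day (15 without 1-day replicate 1 and 15 without 2-week replicate 4). For 4 against 2 weeks this held in 3: 6 without 2-week replicate 3, and 7 without 4-week replicate 1 or 4. For 8 against 4 weeks it held in 7: 86, 7, 10 and 11 without 4-week replicates 2, 3, 4 and 5, and 11, 14 and 15 without 8-week replicates 1, 2 and 4. For 12 against 8 weeks it held in 5: 15 and 11 without 8-week replicates 1 and 3, and 8, 2 and 3 without 12-week replicates 1, 2 and 3. List calls numbered 28 to 36, and the share of the 10 most abundant differed by 2.97 to 3.61 points. Of 32 list calls 0 were kept with an estimated correlation, 15 tests having an unadjusted p under 0.05. With fry 20 were called, 13 of them among the 32. For the lipid list at 12 weeks against 1 day fry gave a downward adjusted p = 0.0395 where camera's direction was up and not called. The single most abundant miRNA differed by 1.04 points (exact permutation p = 0.413), against 3.32 for the 10.

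Replicate numbers do not pair the libraries: same-numbered libraries of different ages correlated between −0.415 and 0.333 (median −0.031), and 1 of 25 correlated best with its own number. With the replicate block the F test gave 253 calls and 12 weeks against 1 day 267, and no count moved by over 1.5 times. Of the changes named by the rule, 2 lost their call with the block and 113 stayed as they were. The share had p = 0.0625 by an exact sign-flip test, the smallest that 5 pairs allow.

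Among miRNAs named by the rule, log2 changes at 12 weeks against 1 day that turned in sign, and were called in the deposited scaling or the alternative, are given with RLE, TMM, DESeq2 and edgeR in turn. They were 0.58, 0.54, 0.57 and 0.54 for miR-194; 0.23, 0.19, 0.20 and 0.16 for miR-30e-5p; and 0.11, 0.07, 0.10 and 0.067 for let-7i-5p. For miR-144-5p they were 0.083, 0.048, 0.11 and 0.07, for miR-126-3p 0.31, 0.28, 0.32 and 0.29, and for miR-7-3p 0.47, 0.44, 0.49 and 0.45. For miR-92a-3p they were 0.42, 0.39, 0.43 and 0.39, for miR-92b 0.35, 0.32, 0.35 and 0.32, and for miR-25-3p 0.35, 0.32, 0.35 and 0.32. For miR-93-5p they were 0.22, 0.18, 0.22 and 0.19, and for miR-27b-3p 0.23, 0.20, 0.24 and 0.20. miR-155-5p was called with RLE (0.44), TMM (0.41) and DESeq2 (0.44) and not with edgeR (0.40), and miR-363-3p turned with RLE (0.003). Outside the rule miR-143-5p turned from −0.43 to 0.14 with RLE and 0.11 with TMM. Turned and called in neither were miR-143-3p, miR-21-5p, miR-199a-3p, miR-199b-3p, miR-199a-5p and miR-217-5p with all 4, miR-200b with RLE, TMM and DESeq2, miR-144-3p with RLE, and miR-216b with DESeq2 and edgeR. Filters, pseudocounts, the block and fitting only the 2 ages turned none. Leaving out 1 library turned no called change, and 5 near 0 that were not called: miR-148a-3p (−0.021 to 0.168), miR-194 (−0.04 to 0.024), miR-192-5p (−0.019 to 0.064), miR-342-3p (−0.051 to 0.081) and miR-200c (−0.105 to 0.392).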

Other observations

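The groups of neighbouring genes were named, and the idea of testing them arose, after the falls of miR-542-3p and miR-532-5p were seen; the test itself was written before its outcome. Counting identical arm ratios once, the neighbour test on mature miRNAs in the same clusters, and median-ratio (RLE) scaling of groups and arms were also chosen after the result was seen. Some groups of neighbouring miRNA genes beyond the DLK1-DIO3 cluster were lower at 12 weeks than at 1 day in both the deposited and RLE scaling. Neighbours were taken from the RefSeq annotation of goat assembly ARS1.2, as genes at most 10000 bases apart, in which 377 of 405 tested miRNAs were found. All 6 tested products of the miR-424, miR-450 and miR-542 genes were called lower (median log2 change −1.92, and −1.38 with RLE), as were all 8 of the miR-362, miR-500, miR-502a, miR-502b and miR-660 genes (−1.22 and −0.71) and all 4 of miR-34b and miR-34c (−1.96 and −1.54), each of them with RLE too. In the last group miR-34c-5p fell most (−2.80). The miR-195 and miR-497 group went the other way, with 3 of 4 products higher (median 0.61, and 1.11 with RLE). Within the miR-17-92 genes 5 of 11 products fell, miR-18a-5p by 1.75 on the log2 scale, while miR-92a-5p had 0.31 without passing; with RLE 5 were higher and 2 lower, and the group's median turned from −0.30 to 0.29.

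A shared genomic cluster is a candidate explanation for neighbours that change together. The test left out the DLK1-DIO3 list and took 85 precursors in 35 clusters, each with the mean of its arms. The group of miR-542, whose fall had prompted the idea, stayed in the test, so part of the result comes from it. The mean standard deviation of log2 change within clusters was 0.230, against a mean of 0.625 and a lowest value of 0.415 over 10000 random assignments (share at or below 1e-04, the smallest they can give). With the 138 mature miRNAs of the same 35 clusters it was 0.289 against a random mean of 0.681, and for precursors with RLE 0.238 against 0.629. Genes of a cluster can also have near-identical products, which the counting could not always separate, so part of this may come from shared reads.

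The 5p and 3p arms cut from 1 precursor did not always change alike, and age may be a factor. Of 71 precursors kept by a limit of 10 RPM on both arms, 32.4% had an unadjusted p under 0.05 for a changed ratio of arms at 12 weeks against 1 day, where 5% would be expected by chance. The limit did not hold at each age: miR-98-3p had 34.6 RPM at 1 day and 9.61 RPM at 12 weeks, and miR-99a-3p 8.04 and 11.5 RPM. The ratio was called for 18 (limma, adjusted p under 0.05), 7 toward the 5p arm and 11 toward the 3p arm, against at most 5 in 100 shuffles of the labels. miR-199b and miR-199c, both among the 18, are 1 measurement under both names. With it counted once, 16 of 70 were called, 7 toward the 5p arm and 9 toward the 3p arm, and 31.4% had an unadjusted p under 0.05. The 3p arm of miR-199b (3588 and 2997 RPM) stood close to that of miR-199a (3597 and 3006 RPM), so its ratio may rest on shared reads. The smallest p was for miR-335, whose 5p arm fell from 13880 to 2996 RPM while its 3p arm had 656 ± 164 and 479 ± 115 RPM (log2 change of the ratio −1.78 ± 0.20, adjusted p = 1.08e-07). miR-29a shifted toward its abundant 3p arm (−0.72 ± 0.10) and miR-362 toward its 5p arm (0.79 ± 0.13). For let-7a the ratio moved toward the 5p arm (0.94 ± 0.16); its arms were called in opposite directions in the deposited scaling, but with RLE let-7a-3p was not called lower (log2 change −0.04, adjusted p = 0.818). With RLE 16 ratios were called, all among the 18. Entries that share reads with other let-7 members can move the let-7a ratio.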
